A study of Rattus norvegicus with 16 samples.

How the data were processed

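Bulk RNA sequencing measured gene expression in the infarct zone of rat hearts in 16 libraries, 4 in each of 4 groups. Per the labels' protocols, total RNA was isolated with a column kit that included DNase digestion, mRNA was purified from it, libraries were built with a NEBNext Ultra RNA kit, and sequencing ran on an Illumina HiSeq instrument. The group and the replicate number of each library came from the labels. The labels do not say that the 4 libraries of a group came from separate animals, so the p-values measure the spread between these samples, which may be technical in part.

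The authors deposited expected counts per gene, an estimate of the reads from each gene that need not be whole, in 1 table of 17085 genes. The authors also deposited TPM (transcript abundance scaled for gene length and depth) for the same genes and libraries. Per the submitters' processing notes, STAR 2.7.3a and RSEM 1.3.1 were used with genome build rn7. The gene annotation and the strand setting are not given in the sources used here. Of the deposited expected counts, 0.785% were not whole, and all were rounded to whole numbers. The deposited TPM of a library summed to less than the total that defines the unit over the genes of the table, so some genes that shared that total are not in it. Gene names were used as the table gives them. A reference table of the GRCr8 assembly, another build than rn7, served only to check names: 15039 were its current symbols, 857 were older symbols and 1189 were in neither. Antisense and overlapping genes cannot be separated without a known strand setting. Of the tested genes, 483 had counts identical to those of another gene in every library and are uncertain for that reason.

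Library totals lay between 10940685 and 14456186 counts. Genes with too few counts for the group sizes were removed with edgeR's default filter by expression, which left 11376 genes. TMM factors scaled the libraries. Levels are given as CPM, counts scaled to a common total with the TMM factors, as mean ± SD over the 4 libraries of a group. The main test was edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3) with robust estimation, 1 coefficient per group and all 16 libraries in one fit, and p-values were adjusted by the Benjamini-Hochberg method over all tested genes. A gene was called changed at an adjusted p under 0.05. The common biological coefficient of variation was 0.403. Differences between groups are on the log2 scale with the standard error (SE) of the fit, and the adjusted p given beside a gene is from this test.

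The script was tested on simulated counts drawn from the real means and library sizes, with 200 genes changed by known folds. For MI_stiff against MI, with 11112 simulated genes in the test, it recovered 23% of the 2-fold and 75% of the 4-fold changes, and 5 of its 103 calls were false. For MI_stiff against MI_soft, with 11163 genes, it recovered 21% and 73%, and 11 of 105 calls were false. In these simulations changes of 2-fold were thus mostly missed with 4 libraries per group and this spread. Each comparison was simulated in a single draw, and the libraries of a group shared the same means. Libraries with few genes detected were not simulated, so these rates may not hold for the real libraries. A simulated rise of the cell cycle list in MI_stiff against MI was called in 10 of 10 draws, with 0 calls of other lists. The simulated genes varied independently of each other. The 0 calls therefore do not show how often the list test errs when genes of a list vary together.

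Gene lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01 between genes, adjusted over the lists of a comparison. Camera compares the genes of a list with all other genes. The same test was run with the correlation estimated from the residuals, which widens the error of a list whose genes vary together. The 32 lists held 664 entries, of which 561 had a row and 517 were tested; 31 lists had the 5 tested members required. The lists were cardiomyocyte contractile proteins, cardiomyocyte calcium handling and ion channels, ventricular wall stress, fatty acid oxidation, respiratory chain and tricarboxylic acid cycle, glycolysis and glucose uptake, collagens and matricellular proteins, matrix crosslinking and proteolysis, activated fibroblasts, resting fibroblasts, TGF-beta signalling, cell-matrix adhesion and mechanosensing, YAP and TAZ target genes, macrophages and monocytes, multinucleated giant cells and osteoclast-type macrophages, neutrophils, lymphocytes, MHC class II antigen presentation, interferon response, inflammatory cytokines and chemokines, cell cycle, endothelial cells, angiogenic factors and hypoxia response, smooth muscle cells and pericytes, epicardium and mesothelium, adipocytes, Schwann cells and nerve, cartilage and bone matrix, atrial myocardium, skeletal muscle and immediate early genes. The list of red blood cells had 3 tested members and was not tested. Some genes stand in more than 1 list. For each list the members called over all genes are counted, and beside them those called when p-values were adjusted over the list alone.

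The groups, comparisons, lists, main tests and the first set of other settings were fixed before the data were examined. So was the rule for named genes. For each of 4 comparisons (MI against Sham, each hydrogel against MI, and the hydrogels against each other) it took the 5 genes with the largest rise and the 5 with the largest fall among called genes with a mean log2 CPM of at least 1, no overlap between the libraries of the groups and a gene symbol that is not a placeholder. It also took up to 3 called members of each list with the smallest p, or 1 member given as a value where none was called. It added Nppa, Nppb, Myh6, Myh7, Atp2a2, Col1a1, Col3a1, Postn, Acta2, Ccn2, Cd68 and Gja1 in every comparison. The text leaves out list members of the middle part for lists summarised by counts. Acta2 is not analysed here, and 1 gene taken by the rule in MI_stiff against MI is not reported here. Genes named outside the rule are said to be chosen after their values were seen.

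That first set was DESeq2 1.42.0, RLE and upper-quartile factors, no filter on low counts and a stricter one (a CPM of at least 1 in 4 libraries), limma-voom, limma on log2(TPM + 1) and log2(TPM + 0.1), fits of the 2 groups compared only, the replicate number as a block, a log2 difference of at least 1 in size, and leaving out each library in turn. For lists they were the estimated correlation, limma's fry, RLE factors, the block and leaving out each library. Added after seeing the data were fits without the 4 libraries that had fewer than 12000 genes with a count (MI 2, MI 3, MI 4 and MI_soft 4, which leaves MI 1 as the only MI library, assumed to vary like the other groups), limma-voom with library quality weights, fits without the 13 mitochondrially encoded genes, and fits with a trend on effective gene length removed. Effective length was the ratio of counts to TPM and was known for 96.54% of the tested genes. Comparisons that share libraries were set against 20 simulations of unchanged groups and against splits of the shared libraries into pairs. For each count of changed genes, all 35 splits of the 8 libraries into 4 and 4 were fitted. No pair of libraries within a group differed by as little as sampling noise. In a chi-square test of their counts, all pairs differed by between 10.2 and 192.2 per gene.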

Results

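Gene expression was measured in the infarct zone of rat hearts in 4 groups of 4 libraries. Sham animals had control surgery, MI animals had the left anterior descending coronary artery ligated, and MI_soft and MI_stiff animals were ligated and treated with a soft or a stiff hydrogel, a water-swollen polymer network that was injected into the heart muscle. The label for RNA extraction names MI/R, a usual term for infarction with reperfusion, so whether blood flow was restored after ligation is not given in the sources used here. Each library held between 10940685 and 14456186 expected counts over 17085 genes, of which 11376 passed the filter on low counts. The number of genes with a count was 12294 ± 110 in Sham, 11383 ± 1015 in MI, 12467 ± 465 in MI_soft and 12314 ± 329 in MI_stiff (mean ± SD, n = 4 each). It was lowest in MI 2 (10470), MI 3 (10958), MI 4 (11283) and MI_soft 4 (11785), whereas MI 1 had 12820. Mitochondrially encoded genes took 41.69% ± 6.33 of the counts in Sham, 39.7% ± 8.2 in MI, 36.63% ± 4.21 in MI_soft and 37.22% ± 8.47 in MI_stiff (SD, n = 4). Correlations of log2 CPM across genes, which are not independent replicates, lay between 0.9724 and 0.9836 within Sham, 0.8682 and 0.9091 within MI, 0.8545 and 0.9769 within MI_soft and 0.9271 and 0.9572 within MI_stiff. MI 1 correlated at 0.957 to 0.964 with MI_soft 1, 2 and 3, and at 0.873 to 0.898 with the other MI libraries. The first principal component held 39.6% of the variance and the next 15.8%.

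**Figure D1:**
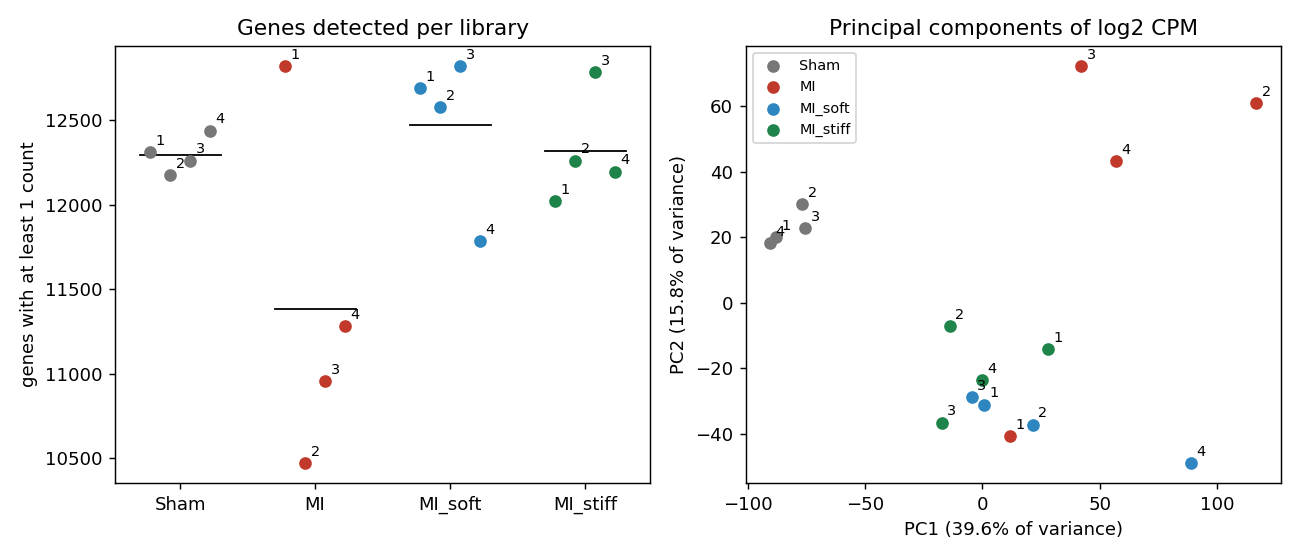
The left panel gives the genes with at least 1 count in each library, with a line at the group mean (n = 4), and the right panel the first principal components of log2 CPM, with 39.6% and 15.8% of the variance, each point being 1 library with its replicate number. MI 2, 3 and 4 and MI_soft 4 lie between 10470 and 11785 genes, under the other 12 libraries, and MI 1 lies among the libraries of the hydrogel groups in the right panel.

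Comparing MI with Sham addressed what coronary ligation does to the infarct zone. Of the genes of cardiomyocytes and their energy metabolism, 9 of 15 contractile (with 1 higher), 17 of 20 calcium handling (with 1 higher), 21 of 26 fatty acid oxidation and 27 of 43 respiratory chain genes were lower in MI. With an estimated correlation these lists had adjusted p = 0.345, 0.165, 0.165 and 0.213. Higher were 14 of 16 activated fibroblast (with 1 lower), 13 of 15 resting fibroblast (with 1 lower) and 18 of 24 collagen and matricellular genes, with adjusted p = 0.0448, 0.0563 and 0.165 with an estimated correlation. Myh6, the adult alpha isoform of cardiac myosin, fell by 3.24 ± 0.43 on the log2 scale (SE), from 20670 ± 4390 to 2186 ± 1170 CPM (SD, n = 4 per group). Atp2a2, the calcium pump of the sarcoplasmic reticulum, fell by 2.58 ± 0.26, from 14960 ± 1140 to 2509 ± 989 CPM. Postn, a matricellular protein of activated fibroblasts, rose by 5.26 ± 0.41, from 12.0 ± 2.79 to 460 ± 226 CPM, and Col3a1, a fibrillar collagen, rose by 2.96 ± 0.25 to 10030 ± 2200 CPM. In all, 4165 of 11376 genes changed, 2296 higher and 1869 lower, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Of all 11376 genes 4322 (38%) had no overlap between the libraries of the groups, a separation that chance gives for 2.86% of genes. Genes that rose were 55.1% of the calls, against 50% with DESeq2 (2344 higher and 2347 lower). The majority turned to lower with limma-voom (1892 higher and 2338 lower, 44.7%), with library quality weights (2518 and 2536, 49.8%) and without MI 1 (2293 and 2476, 48.1%). In this comparison MI 2, 3 and 4 had fewer genes with a count than any Sham library, and without the low-detection libraries, which leaves MI 1 alone, 3297 genes changed, 2405 of them among the 4165.

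The largest rises by the fixed rule were those of Ca3 (carbonic anhydrase of slow muscle), with 83.5 ± 149 against 0.330 ± 0.660 CPM, Ccn5 (7.58 ± 0.46), Myl1 (7.25 ± 0.82), Thbs4 (7.09 ± 0.49) and Ltbp2 (6.14 ± 0.38), with edgeR adjusted p-values between 2.15e-08 and 0.00793. MI 1 carries part of these: it had log2 CPM of 8.264 for Ca3 (1.322 to 3.76 in the other MI libraries) and 8.438 for Myl1 (4.92 to 6.199). Without it the log2 differences were 4.64 for Ca3, which then does not lead, and 5.88 for Myl1. All Sham counts of Ca3 were in Sham 3, and without that library its fitted difference was 13.1, against a group at 0. The largest falls were those of Asb15 (-4.48 ± 0.72), Tbx20 (-4.45 ± 1.05), Gfod1 (-4.39 ± 1.19), Iqgap2 (-4.37 ± 0.97) and Pkia (-4.36 ± 0.79), with adjusted p-values between 0.00015 and 0.00842. Pkia fell from 126 ± 16.3 to 6.03 ± 6.53 CPM, and the other 4 of these had means of 0.535 to 0.988 CPM in MI. Without MI 1 the differences were -6.13 for Tbx20, -8.54 for Gfod1, -5.04 for Iqgap2 and -5.48 for Pkia, and without MI 3 that of Asb15 was -5.34. Without the low-detection libraries, which leaves MI 1 alone, the differences were smaller in size. They were -4.4 for Asb15, -2.94 for Tbx20, -2.56 for Gfod1, -3.41 for Iqgap2 and -3.02 for Pkia.

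Of 15 tested contractile proteins 9 fell, 1 rose and 5 did not pass (9 and 1 adjusted over the list alone). Contractile proteins had camera adjusted p = 0.00818 and adjusted p = 0.345 with an estimated correlation. Myom2 of the sarcomeric M-band fell by 1.94 ± 0.35, while Csrp3, a Z-disc protein, rose by 1.08 ± 0.22 with edgeR adjusted p = 0.00112, and at 0.207 without the low-detection libraries. Of 20 calcium handling and ion channel genes 17 fell and 1 rose (17 and 1 adjusted over the list alone). Calcium handling genes had camera adjusted p = 1.77e-08 and adjusted p = 0.165 with an estimated correlation. Pln, the inhibitor of the calcium pump, fell by 2.06 ± 0.22 and Gja1, the main ventricular gap junction protein, fell by 2.14 ± 0.31. Of 26 fatty acid oxidation genes 21 fell and 5 did not pass (23 fell adjusted over the list alone), among them Acsl1 (-2.80 ± 0.30), Hadh (-2.36 ± 0.25) and Hadhb (-2.30 ± 0.26). Fatty acid oxidation had camera adjusted p = 2.57e-10 and adjusted p = 0.165 with an estimated correlation. Of 43 genes of the respiratory chain and tricarboxylic acid cycle 27 fell and 16 did not pass (30 fell adjusted over the list alone), with Cs at -2.57 ± 0.30 and Ndufs1 at -1.92 ± 0.24. The respiratory chain list had camera adjusted p = 2.57e-10 and adjusted p = 0.213 with an estimated correlation. Of 13 glycolysis and glucose uptake genes 6 fell and 7 did not pass (6 adjusted over the list alone). Glycolysis had camera adjusted p = 0.0488 and adjusted p = 0.373 with an estimated correlation. Of 14 wall stress genes 10 rose and 1 fell (11 and 1 adjusted over the list alone). Wall stress had camera adjusted p = 0.000778 and adjusted p = 0.187 with an estimated correlation. Nppa, an atrial natriuretic peptide gene re-expressed in stressed ventricle, rose by 5.42 ± 0.58 from 111 ± 89.0 to 4739 ± 1310 CPM (6.08 without Sham 2), Ankrd23 rose by 3.03 ± 0.36 and Nppb rose by 1.51 ± 0.26. Myh7, the slow beta isoform of cardiac myosin, rose by 0.86 ± 0.31 with edgeR adjusted p = 0.0362, a call lost without Sham 1 (0.0941), Sham 2 (0.0759), Sham 3 (0.0525), Sham 4 (0.0516), MI 1 (0.0838), MI 3 (0.0671) or MI 4 (0.0531).

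Of 24 collagens and matricellular proteins 18 rose and 0 fell (19 rose adjusted over the list alone). The collagen list had camera adjusted p = 5.76e-09 and adjusted p = 0.165 with an estimated correlation. Fn1 rose by 3.62 ± 0.28 and Col1a1 rose by 2.47 ± 0.36 from 459 ± 82.2 to 2548 ± 1570 CPM. Of 27 genes of matrix crosslinking and proteolysis 17 rose (17 adjusted over the list alone), with Timp1, an inhibitor of matrix proteases, at 4.62 ± 0.42 and Mmp2 at 2.52 ± 0.24. Matrix crosslinking and proteolysis had camera adjusted p = 8.14e-07 and adjusted p = 0.0895 with an estimated correlation. Of 16 genes of activated fibroblasts 14 rose and 1 fell (14 and 2 adjusted over the list alone), and this was the list that also held with an estimated correlation (adjusted p = 0.0448). Activated fibroblasts had camera adjusted p = 2.84e-08. Sfrp2 of this list rose by 5.98 ± 0.52. Of 15 genes of resting fibroblasts 13 rose and 1 fell (13 and 1 adjusted over the list alone), with Pi16 at 3.91 ± 0.33 and Fbln1 at 2.76 ± 0.21. Resting fibroblasts had camera adjusted p = 2.84e-08 and adjusted p = 0.0563 with an estimated correlation. Of 20 TGF-beta signalling genes 11 rose and 2 fell (11 and 2 adjusted over the list alone), and Ccn2, a matricellular target of this pathway, rose by 3.74 ± 0.46. TGF-beta signalling had camera adjusted p = 0.00313 and adjusted p = 0.191 with an estimated correlation. Of 17 YAP and TAZ targets, genes that respond to mechanical load, 10 rose and 2 fell (10 and 2 adjusted over the list alone). YAP and TAZ targets had camera adjusted p = 0.00969 and adjusted p = 0.301 with an estimated correlation.

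Of 22 macrophage and monocyte genes 17 rose (18 adjusted over the list alone), among them Gpnmb (3.55 ± 0.48), Cd68 (2.67 ± 0.54, and 2.08 without MI 1) and Cd14 (2.42 ± 0.36). Macrophages and monocytes had camera adjusted p = 1.39e-05 and adjusted p = 0.327 with an estimated correlation. Of 15 immediate early genes 12 rose (13 adjusted over the list alone), with Fos at 3.32 ± 0.44 and Egr2 at 3.27 ± 0.42. Immediate early genes had camera adjusted p = 1.37e-05 and adjusted p = 0.165 with an estimated correlation. Of 15 inflammatory cytokines and chemokines 9 rose (9 adjusted over the list alone). Inflammatory cytokines and chemokines had camera adjusted p = 0.00818 and adjusted p = 0.196 with an estimated correlation. Of 10 genes of MHC class II antigen presentation 5 rose (8 adjusted over the list alone). MHC class II had camera adjusted p = 0.0213 and adjusted p = 0.373 with an estimated correlation. Of 12 genes of giant cells and osteoclast-type macrophages 5 rose and 1 fell (5 and 1 adjusted over the list alone). Giant cells had camera adjusted p = 0.0488 and adjusted p = 0.345 with an estimated correlation. Of 9 epicardial genes 5 rose (7 and 1 lower adjusted over the list alone). The epicardial list had camera adjusted p = 0.00843 and adjusted p = 0.327 with an estimated correlation. Of 5 skeletal muscle genes 4 rose (4 adjusted over the list alone). Skeletal muscle had camera adjusted p = 0.0295 and adjusted p = 0.373 with an estimated correlation. Of 13 Schwann cell genes 5 rose (5 adjusted over the list alone). Schwann cells had camera adjusted p = 0.0431 and adjusted p = 0.274 with an estimated correlation. Of 6 genes of cartilage and bone matrix 4 rose (5 adjusted over the list alone; camera adjusted p = 0.0488, and adjusted p = 0.34 with an estimated correlation).

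The other 10 lists did not pass in MI against Sham. Their camera adjusted p-values were 0.0505 for interferon response (4 of 21 rose), 0.0515 for smooth muscle cells and pericytes (8 rose and 3 fell of 15), 0.127 for endothelial cells (4 rose and 1 fell of 15), 0.132 for cell-matrix adhesion and mechanosensing (9 rose and 3 fell of 19), 0.201 for adipocytes (5 rose and 1 fell of 11), 0.406 for neutrophils (3 of 6 rose), 0.667 for atrial myocardium (1 of 7 rose), 0.764 for angiogenic factors and hypoxia response (6 rose and 7 fell of 23) and 0.82 for cell cycle (1 of 20 rose, with a median of -0.07, a mean of 0.09 and a test direction of higher). For lymphocytes it was 0.406 with 0 of 20 genes called, a median of -0.03 and a mean of 0.27, and a test direction of lower. Tagln and Actg2, contractile genes of smooth muscle, rose by 3.73 ± 0.44 (3.14 without MI 2) and 5.10 ± 0.58. Of 3 red blood cell genes 1 fell, with no test of the list. Lists that lost their call with 1 library left out were MHC class II (0.0907 without MI 1), contractile proteins (0.0507 without MI 1), skeletal muscle (0.0574 without MI 1), Schwann cells (0.0738 without Sham 2, 0.073 without MI 1 and 0.0584 without MI_soft 4) and giant cells (0.0557 without Sham 2, 0.0576 without Sham 3, 0.104 without MI 1 and 0.088 without MI_soft 4). Cartilage and bone matrix lost it without Sham 2 (0.0643), Sham 4 (0.0524), MI 1 (0.0721), MI 2 (0.0583) or MI_soft 4 (0.0694), and glycolysis without Sham 3 (0.0786), MI 1 (0.0574), MI 2 (0.0519), MI 3 (0.157) or MI_stiff 4 (0.0502). Without the low-detection libraries the epicardial list had camera adjusted p = 0.91, glycolysis 0.197 and cartilage and bone matrix 0.117.

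**Figure D2:**
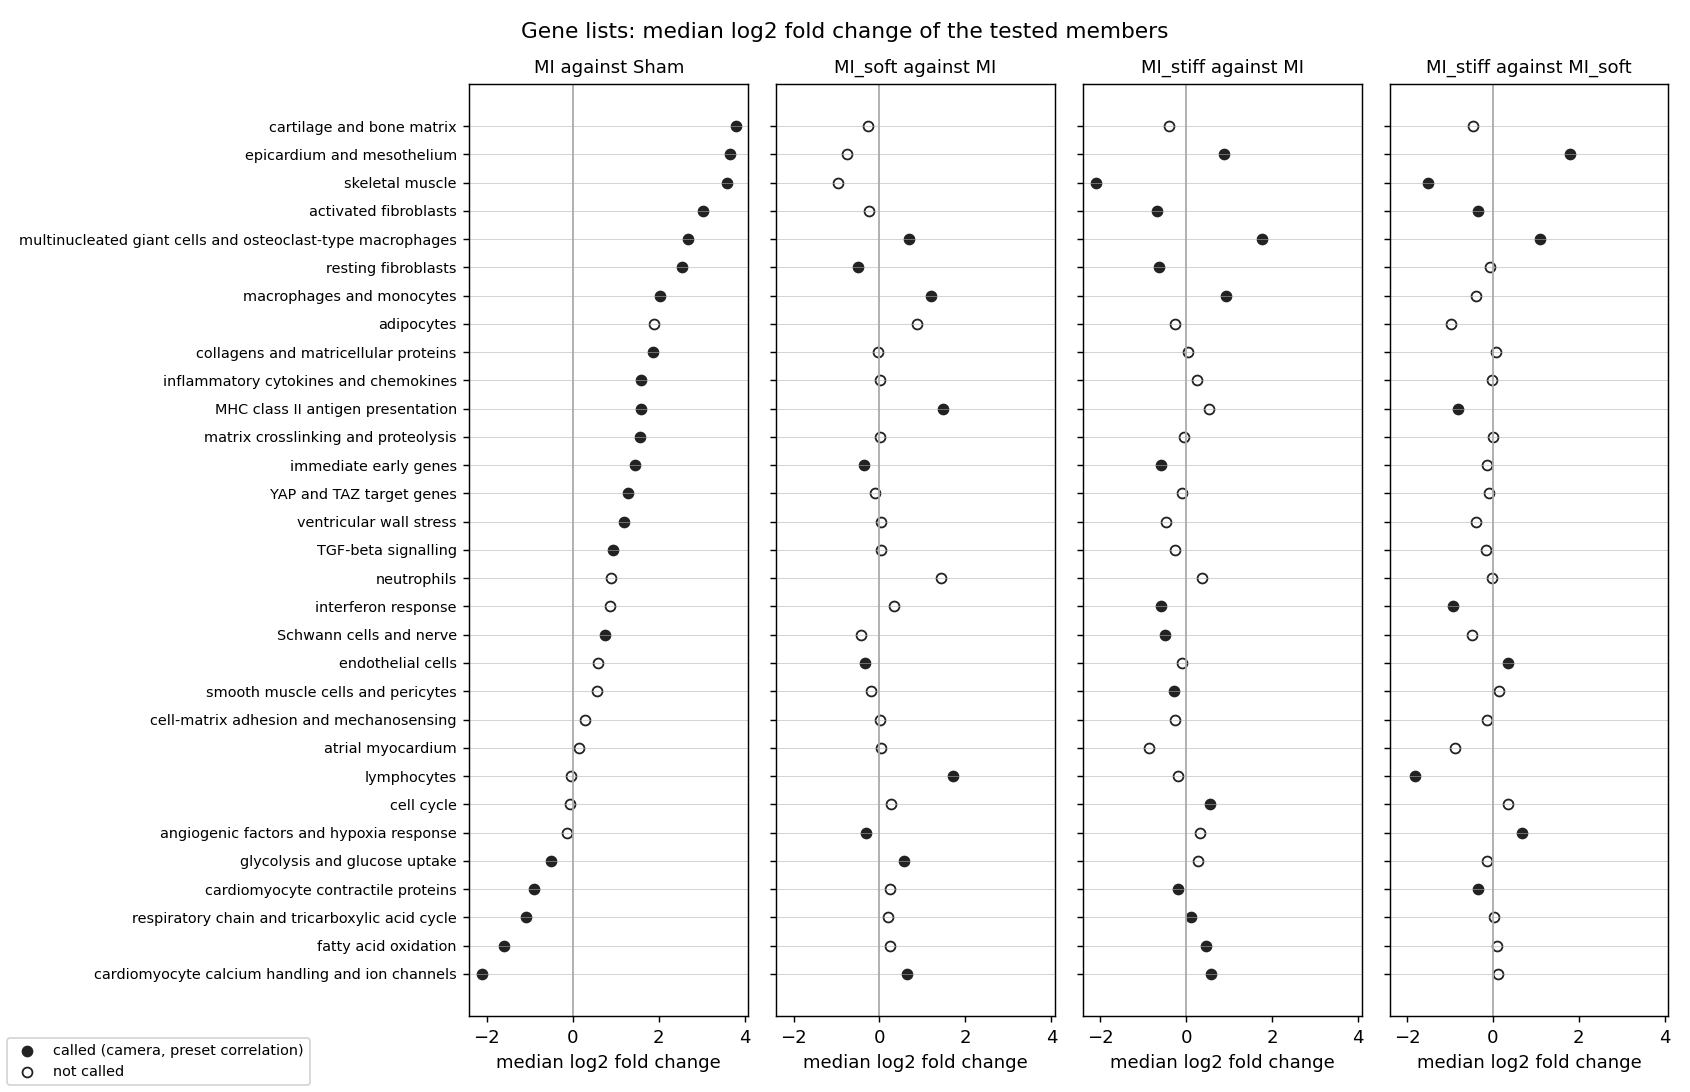
Median log2 fold change of the tested members of each of 31 gene lists (horizontal axis) in 4 comparisons, 1 point per list, filled where camera with its preset correlation called the list and open where it did not. In MI against Sham the list of activated fibroblasts lies at 3.03 and that of calcium handling and ion channels at -2.11.

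Comparing MI_soft with MI addressed the effect of the soft hydrogel on the ligated heart. Only 3 genes passed, all lower with the gel. Mmrn1, which encodes multimerin of platelets and lymphatic endothelium, fell by 2.06 ± 0.33 from 75.6 ± 20.7 to 18.1 ± 7.09 CPM (SD, n = 4). Cirbp, a cold-inducible RNA-binding protein, fell by 1.497 ± 0.234 from 47.8 ± 11.9 to 16.9 ± 2.79 CPM, and Nck2, a signalling adaptor, fell by 1.31 ± 0.21 from 28.3 ± 6.60 to 11.4 ± 2.50 CPM, each with edgeR adjusted p = 0.0316. The macrophage, lymphocyte and MHC class II lists were higher in MI_soft by camera with its preset correlation, with 0 members passing by edgeR over all genes, and had adjusted p = 0.501, 0.285 and 0.501 with an estimated correlation. The mean log2 CPM of each list in MI 1 lay within the range of MI_soft (5.84 against 5.38 to 6.55 for macrophages, 1.54 against 1.28 to 2.80 for lymphocytes and 4.84 against 4.79 to 6.14 for MHC class II). That of MI 2, 3 and 4, which are low-detection libraries, lay under it (4.04 to 4.51, -1.39 to -0.327 and 3.48 to 4.12).

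The count of genes higher in MI_soft was 0 by edgeR's quasi-likelihood test, while 1761 genes had an unadjusted p under 0.05, DESeq2 called 135 higher and 158 lower, and limma-voom 3 higher and 4 lower. The count of 3 became 0 without Sham 1, 2, 3 or 4, MI 2, MI 4, MI_soft 1, MI_soft 4 or MI_stiff 1, and 1 without MI 3, and it became 1508 (912 higher and 596 lower) without MI 1. The 3 genes had adjusted p-values of 0.0526 to 0.0882 without 1 Sham library, 0.158 to 0.189 without MI 2, 0.0589 without MI 3, 0.128 to 0.145 without MI 4, 0.165 without MI_soft 1, 0.0623 without MI_soft 4 and 0.0644 without MI_stiff 1. Nck2 alone was lost without MI_soft 2 (0.109), MI_stiff 2 (0.0565), MI_stiff 3 (0.0523) or MI_stiff 4 (0.0714), and Mmrn1 and Cirbp without MI_soft 3 (0.0713 and 0.081). The fit without the low-detection libraries called 11 genes, with 0 of the 3 among them.

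Of 22 macrophage and monocyte genes 0 passed over all genes and 11 were higher adjusted over the list alone (median 1.20). Macrophages and monocytes had camera adjusted p = 2.3e-08 and adjusted p = 0.501 with an estimated correlation. Lyz2, a lysozyme of myeloid cells, stood at 1754 ± 1050 CPM against 375 ± 157 (difference 2.23 ± 0.47, edgeR adjusted p = 0.0914). Of 20 lymphocyte genes 2 were higher adjusted over the list alone (median 1.70), and Jchain, the joining chain of secreted antibodies, stood at 125 ± 105 against 5.68 ± 8.76 CPM (edgeR adjusted p = 0.0914). Lymphocytes had camera adjusted p = 2.11e-09 and adjusted p = 0.285 with an estimated correlation. Of 10 MHC class II genes 5 were higher adjusted over the list alone (camera adjusted p = 0.003, and adjusted p = 0.501 with an estimated correlation), with Cd74, the invariant chain, at 1273 ± 710 against 408 ± 236 CPM (edgeR adjusted p = 0.153). Of 12 giant cell and osteoclast-type genes 3 were higher and 1 lower adjusted over the list alone (camera adjusted p = 0.0182, and adjusted p = 0.501 with an estimated correlation). Without the low-detection libraries camera gave 0.684 for macrophages with the direction turned to lower, 0.585 for lymphocytes, 0.748 for MHC class II and 0.348 for giant cells. The same fit, with MI 1 as the single MI library, called lists that had not passed: respiratory chain (1.07e-08), fatty acid oxidation (0.000746) and cell cycle (0.000746) higher, and skeletal muscle (6.12e-17), collagens (0.000517) and interferon response (0.02) lower in MI_soft. It also called the epicardial list (0.0036) higher, turned from lower in the main fit (0.12).

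Higher lists in MI_soft were also calcium handling and ion channels (5 of 20 adjusted over the list alone; camera adjusted p = 0.00796, and adjusted p = 0.634 with an estimated correlation; 0.151 without MI 2) and glycolysis (1 of 13 adjusted over the list alone; camera adjusted p = 0.00925, and adjusted p = 0.501 with an estimated correlation; 0.077 without MI_soft 4 and 0.748 without the low-detection libraries). Pln stood at 1135 ± 252 against 585 ± 94.7 CPM and Atp2a2 at 4857 ± 639 against 2509 ± 989 CPM, with edgeR adjusted p-values of 0.0914 and 0.115. Lower lists were resting fibroblasts (2 of 15 adjusted over the list alone; camera adjusted p = 0.000481, and adjusted p = 0.285 with an estimated correlation) and endothelial cells (4 of 15 adjusted over the list alone; camera adjusted p = 0.0009, and adjusted p = 0.285 with an estimated correlation; 0.348 without the low-detection libraries). The lists of angiogenic factors (1 of 23 adjusted over the list alone; camera adjusted p = 0.00925; 0.115 without MI_soft 4 and 0.68 without the low-detection libraries) and of immediate early genes (5 of 15; 0.0108; 0.0845 without MI 1 and 0.253 without MI 2) were lower too, and both had an adjusted p = 0.501 with an estimated correlation. The other fixed genes had log2 differences between -0.53 ± 0.34 for Postn and 1.53 ± 0.50 for Cd68, with edgeR adjusted p-values of 0.184 to 0.995 for Nppa, Nppb, Myh6, Myh7, Col1a1, Col3a1, Postn, Ccn2, Cd68 and Gja1.

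Comparing MI_stiff with MI addressed the effect of the stiff hydrogel. Of 12 genes of multinucleated giant cells and osteoclast-type macrophages, the fused macrophages of bone and of foreign-body reactions, 5 were higher in MI_stiff, and of 15 genes of smooth muscle cells and pericytes 4 were lower. Camera with its preset correlation called both lists, and with an estimated correlation they had adjusted p = 0.197 and adjusted p = 0.441. Mmp12, the macrophage elastase, rose by 6.37 ± 0.94 from 6.61 ± 8.89 to 561 ± 283 CPM (SD, n = 4; a rise of 8 without MI 1) and Gpnmb, a glycoprotein of lipid-laden and osteoclast-type macrophages, rose by 3.27 ± 0.47 from 103 ± 64.3 to 993 ± 503 CPM. Ccl21, a chemokine of lymphatic vessels and lymphoid tissue, fell by 2.89 ± 0.40 from 387 ± 216 to 52.1 ± 13.7 CPM, and Thbs4, a matricellular protein, fell by 2.25 ± 0.39 from 353 ± 84.7 to 73.9 ± 24.4 CPM. In all, 56 genes rose and 79 fell by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and 1938 had an unadjusted p under 0.05. DESeq2 called 305 higher and 278 lower (52.3% higher, against 41.5%), and limma called 72 higher and 19 lower on log2(TPM + 1) and 41 and 6 on log2(TPM + 0.1). Of all genes tested 897 (7.89%) had no overlap between the groups, against a chance share of 2.86%. Genes of the same libraries are not independent, and MI 2, 3 and 4 are low-detection libraries, so this excess is no test of the gel. Of the 135, 11 had counts identical to those of another gene.

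The count of 135 moved by over 1.5 times with any 1 library left out other than MI 3 (190 genes). It was 50, 55, 56 and 52 without Sham 1 to 4, 1253 without MI 1, 15 without MI 2, 11 without MI 4, 53, 59, 59 and 534 without MI_soft 1 to 4, and 56, 47, 21 and 26 without MI_stiff 1 to 4. Without the low-detection libraries 215 genes changed, 26 of them among the 135. Of 35 genes of this comparison named here, Mmp12, Hk3, Ccl21, Gpnmb and Hmox1 kept their calls in all 16 fits with 1 library left out. Of the other named genes 26 lost theirs without MI 2 (edgeR adjusted p 0.0533 to 0.167), 6 without MI 3 (0.0518 to 0.0899), 28 without MI 4 (0.054 to 0.134), 19 without MI_stiff 1 (0.0622 to 0.0806), 19 without MI_stiff 2 (0.0509 to 0.141), 26 without MI_stiff 3 (0.0626 to 0.147) and 24 without MI_stiff 4 (0.0649 to 0.128). The same held for 16, 17 and 14 named genes without MI_soft 1, 2 and 3 (0.0521 to 0.0644) and for 18, 15, 14 and 15 without Sham 1 to 4 (0.0505 to 0.0697); these groups enter the comparison only through the shared fit.

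Of 12 giant cell and osteoclast-type genes 5 rose and 7 did not pass (7 rose adjusted over the list alone). Giant cells had camera adjusted p = 1.62e-05 and adjusted p = 0.197 with an estimated correlation. MI_stiff 2 stood apart, with a mean log2 CPM over the list of 2.983 against 4.444 to 4.517 in the other MI_stiff libraries, inside the range of MI_soft (2.681 to 3.508) and near MI 1 (2.603). The list kept its camera call without it. Dcstamp, a fusion protein of osteoclasts and giant cells, stood at 6.40 ± 3.74 CPM in MI_stiff and at 0.0615 ± 0.123 in MI, where its 4 counts were all in MI 1 (log2 difference 6.27, and 9.35 without MI 1; edgeR adjusted p = 0.0142, and 0.054 without MI 4). Ocstamp, its relative, stood at 12.9 ± 9.37 against 0.215 ± 0.430 CPM, with 14 counts in MI 1 and 0 in the other MI libraries. Its log2 difference was 5.65 (10.4 without MI 1, edgeR adjusted p = 0.0432), and its log2 CPM in MI_stiff 2 (-0.65) lay under that in MI 1 (0.0216). Spp1, osteopontin, rose by 2.20 ± 0.51 (edgeR adjusted p = 0.0423). Ocstamp and Spp1 were chosen after their values were seen. Each lost its call in 13 of the 16 fits with 1 library left out (edgeR adjusted p up to 0.133 for Ocstamp and 0.147 for Spp1). Ctsk, the collagen-degrading protease of osteoclasts, rose by 1.32 ± 0.28 from 98.8 ± 11.4 to 246 ± 111 CPM (adjusted p = 0.0366, and 0.0505 to 0.099 without Sham 2, MI 2, MI 4, MI_stiff 1, MI_stiff 3 or MI_stiff 4). Of 22 macrophage and monocyte genes 1 rose, Gpnmb (6 adjusted over the list alone), and Cd68 stood at 75.7 ± 40.6 against 25.4 ± 16.9 CPM (edgeR adjusted p = 0.128). Macrophages and monocytes had camera adjusted p = 1.92e-05 and adjusted p = 0.441 with an estimated correlation. The MI libraries with few genes detected stand on the lower side of this contrast. Without them and MI_soft 4, which leaves MI 1 as the single MI library, Ctsk kept its log2 difference (1.34 ± 0.484 against 1.32 ± 0.278) with a wider SE and had edgeR adjusted p = 0.161. Differences were smaller, with a wider SE, for Mmp12 (4.83 ± 1.51, adjusted p = 0.173), Gpnmb (2.33 ± 0.803, 0.156), Dcstamp (4.65 ± 1.22, 0.0719) and Hmox1 (1.48 ± 0.321, 0.0305), and camera gave 0.00269 for the giant cell list and 0.687 for the macrophage list with the direction turned to lower.

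**Figure D3:**
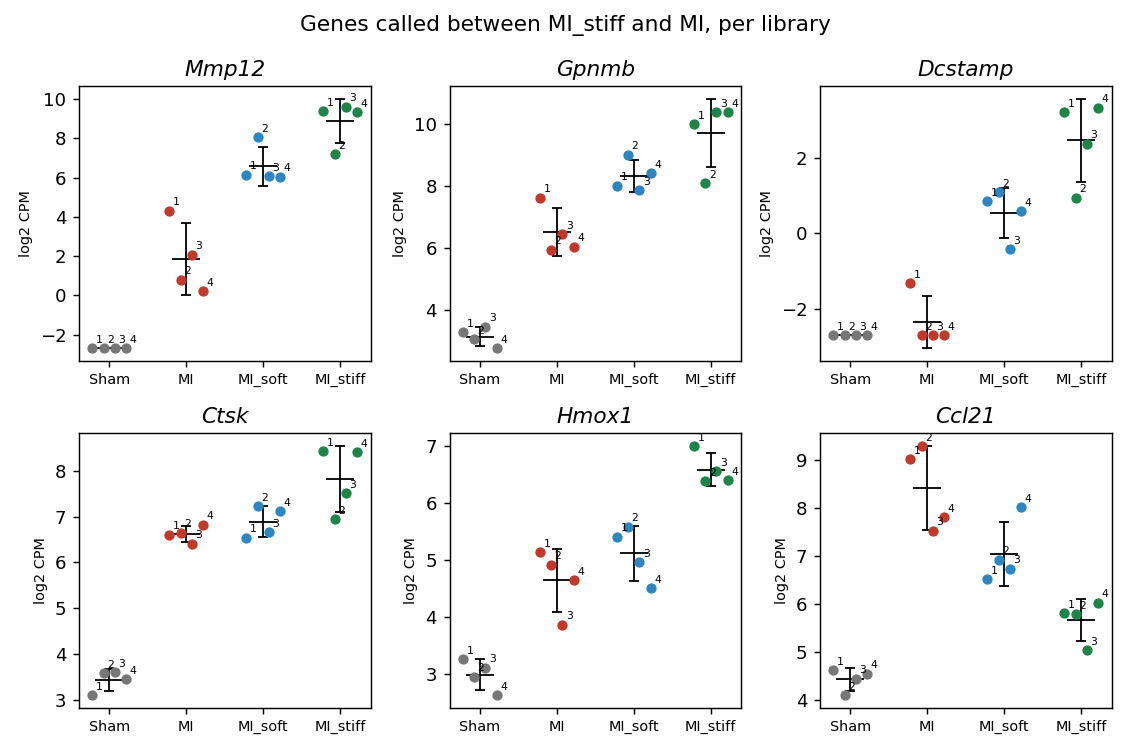
Expression (log2 CPM) of Mmp12, Gpnmb, Dcstamp, Ctsk, Hmox1 and Ccl21 in the 4 groups, each point being 1 library with its replicate number, with the mean ± SD of the log2 values (n = 4). Mmp12 lies at 4.32 in MI 1 and between 6.04 and 8.05 in MI_soft.

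Other rises by the fixed rule were those of Tnn, a tenascin of tendon and bone (4.18 ± 0.68), Hk3, the hexokinase of myeloid cells (4.09 ± 0.65, and 4.75 without MI 1), and Rab15 (4.01 ± 0.89, and 6.73 without MI 1), with edgeR adjusted p-values of 0.00955 to 0.0389. Without the low-detection libraries, with MI 1 as the single MI library, these rises were 3.58 for Tnn, 3.07 for Hk3 and 2.27 for Rab15. Il1rn, the interleukin 1 receptor antagonist, rose by 3.79 ± 0.62, Plau, the urokinase, rose by 2.56 ± 0.47, and Hmox1, the heme-degrading enzyme, rose by 1.90 ± 0.28 from 26.1 ± 8.81 to 97.5 ± 21.1 CPM. Aplnr, the apelin receptor, rose by 1.47 ± 0.26, Slc2a1, a glucose transporter, rose by 1.27 ± 0.27, and Col5a3 rose by 1.48 ± 0.34. Tnn, Hk3 and Rab15 stand in none of the lists. Of the lists of the other genes, the 15 inflammatory cytokines and chemokines (1 rose, camera adjusted p = 0.483), the 23 angiogenic factors (1 rose, 0.11), the 13 glycolysis genes (1 rose, 0.0608), the 24 collagens and matricellular proteins (1 rose and 1 fell, 0.953, median 0.04 and mean -0.06) and the 27 genes of matrix crosslinking and proteolysis (2 rose, 0.957, median -0.05 and mean 0.69) did not pass. Of 9 epicardial genes Msln, mesothelin, rose by 2.87 ± 0.67, and by 4.02 without MI 2 (1 adjusted over the list alone). The epicardial list had camera adjusted p = 0.0462 and adjusted p = 0.441 with an estimated correlation. That list lost its call without MI 1 (0.306), MI_stiff 2 (0.0642), MI_stiff 3 (0.111) or MI_stiff 4 (0.114).

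Of 15 smooth muscle and pericyte genes 4 fell (4 adjusted over the list alone). Smooth muscle and pericytes had camera adjusted p = 0.0217 and adjusted p = 0.441 with an estimated correlation. Tagln fell by 1.85 ± 0.41 from 337 ± 238 to 93.8 ± 12.5 CPM (1.25 without MI 2), Myl9 fell by 1.80 ± 0.40 and Cnn1 fell by 2.95 ± 0.66 (2.08 without MI 2), and Actg2, chosen after its values were seen, fell by 2.11 ± 0.49. The list lost its call without MI 1 (0.0826), MI 2 (0.0666), MI 4 (0.052) or MI_stiff 1 (0.122). Of 15 resting fibroblast genes 2 fell, Fbln1 (-0.94 ± 0.19) and Gsn (-0.84 ± 0.19), with 8 lower adjusted over the list alone (camera adjusted p = 2.23e-05, and adjusted p = 0.197 with an estimated correlation). Of 16 activated fibroblast genes 2 fell, Tagln and Meox1 (-2.30 ± 0.50), with 5 adjusted over the list alone (camera adjusted p = 0.00266, and adjusted p = 0.354 with an estimated correlation; 0.0615 without MI 1). The largest falls further included Myl1 (-3.24 ± 0.65) and Tpm2 (-2.88 ± 0.53), a light chain of fast skeletal myosin and a tropomyosin, and Cyp21a1 (-2.67 ± 0.59, and -2.01 without MI 2, at 1.92 ± 0.871 CPM in MI_stiff). Myl1 had a mean of 123 CPM in MI with an SD of 150, and its difference was -1.91 without MI 1. Of 5 skeletal muscle genes 1 fell (4 adjusted over the list alone), and its mean log2 CPM was 6.04 in MI 1 against 3.49, 1.51 and 2.46 in MI 2, 3 and 4. Skeletal muscle had camera adjusted p = 0.0107 and adjusted p = 0.441 with an estimated correlation, and 0.157 without MI 1. Tgfb3 fell by 1.18 ± 0.27 and Ccn1, a YAP target, fell by 1.28 ± 0.26, while their lists did not pass (1 of 20 fell, camera adjusted p = 0.132, and 1 of 17 fell, 0.298).

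Of 15 immediate early genes 3 fell and Atf3, a stress-induced transcription factor, rose by 1.56 ± 0.31 (6 fell and 1 rose adjusted over the list alone). Immediate early genes had camera adjusted p = 0.00692 and adjusted p = 0.441 with an estimated correlation, and 0.0623 without MI 2. Fos fell by 1.84 ± 0.41 and Dusp1 fell by 1.12 ± 0.21. Atp2a2 rose by 1.099 ± 0.244 from 2509 ± 989 to 5375 ± 424 CPM, the single call among 20 calcium handling genes (1 adjusted over the list alone; camera adjusted p = 0.000618, and adjusted p = 0.441 with an estimated correlation; 0.214 without the low-detection libraries). Of 26 fatty acid oxidation genes 0 passed by edgeR over all genes, with 7 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.00156, and adjusted p = 0.441 with an estimated correlation). Of 43 respiratory chain genes 1 rose, Cycs, whose counts are identical to those of another gene (5 adjusted over the list alone). The respiratory chain list had camera adjusted p = 0.0268 and adjusted p = 0.624 with an estimated correlation. This list lost its call without MI 1 (0.4), MI 2 (0.167), MI_stiff 1 (0.123) or MI_stiff 4 (0.0604). Nppb fell by 1.11 ± 0.26 from 501 ± 97.2 to 233 ± 55.1 CPM, and of the 14 wall stress genes 1 rose and 1 fell (camera adjusted p = 0.0564). With 0 members passing by edgeR over all genes, camera also called cell cycle higher (0.00112, and adjusted p = 0.388 with an estimated correlation), interferon response lower (0.00137, and adjusted p = 0.441 with an estimated correlation; 0.0539 without the low-detection libraries), Schwann cells lower (0.0217, and adjusted p = 0.388 with an estimated correlation; 0.0826 without MI 1 and 0.0757 without MI_stiff 3) and contractile proteins lower (0.0217, and adjusted p = 0.441 with an estimated correlation; 0.125 without MI 3, 0.0645 without MI_stiff 2 and 0.437 without the low-detection libraries). Myh6 (1.05 ± 0.40), Myh7 (-0.84 ± 0.31), Nppa (-1.17 ± 0.49), Ccn2 (-0.84 ± 0.41), Col3a1 (-0.47 ± 0.23), Col1a1 (0.32 ± 0.34), Gja1 (0.38 ± 0.30) and Postn (-0.16 ± 0.34) did not pass, with edgeR adjusted p-values of 0.176 to 0.849.

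Comparing MI_stiff with MI_soft addressed hydrogel stiffness and is the test of the difference between the effects of the gels. Of the core transcription factors of the circadian clock, Arntl stood higher in MI_stiff by 2.87 ± 0.39 (38.7 ± 18.8 against 5.26 ± 2.17 CPM, SD, n = 4) and Npas2 by 2.82 ± 0.42 (19.2 ± 8.85 against 2.69 ± 1.75 CPM). Dbp, a clock output gene, stood lower at 13.1 ± 15.5 against 226 ± 115 CPM (-4.11 ± 0.67, and -5.4 without MI_stiff 3). Also higher in MI_stiff were Ucp3, a mitochondrial carrier of muscle (2.20 ± 0.28), Aplnr (2.07 ± 0.27), Angptl4, an inhibitor of lipoprotein lipase (1.98 ± 0.36), and Atf3 (1.83 ± 0.31). Also lower were Ighe, an immunoglobulin heavy chain gene, with 8.36 ± 3.18 against 1870 ± 1840 CPM (-7.80 ± 1.39, and -7 without MI_soft 1), and Ccl19, a lymphoid chemokine, with 9.22 ± 3.05 against 57.3 ± 45.5 CPM (-2.64 ± 0.45, and -1.92 without MI_soft 4). These genes, with Nupr1 (-1.81 ± 0.33) and Fmo5 (1.69 ± 0.30, chosen after its values were seen), made up the 11 calls, 7 higher and 4 lower, with edgeR adjusted p-values of 0.00273 to 0.0365.

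At an unadjusted p under 0.05 there were 1631 genes, and DESeq2 called 93 higher and 185 lower (33.5% higher, against 63.6%). With upper-quartile factors 13 were higher and 19 lower (40.6%). Of all genes tested 1291 (11.3%) had no overlap between the groups, which chance gives for 2.86% of genes. This share is no test either, since genes of the same libraries are not independent. The count was 6 without Sham 3, 6 without Sham 4, 55 without MI 1, 57 without MI 3, 7, 17, 6 and 5 without MI_soft 1 to 4, and 4 without MI_stiff 4. Arntl, Npas2, Ucp3 and Aplnr kept their calls in all 16 fits with 1 library left out. Dbp lost its call without MI_soft 4 (edgeR adjusted p 0.0517), MI_stiff 1 (0.051), MI_stiff 2 (0.0675) or MI_stiff 4 (0.107). Of the other 6, some lost theirs without Sham 1 (0.0558), Sham 2 (0.0507 to 0.0612), Sham 3 (0.0542 to 0.0672), Sham 4 (0.0532 to 0.0646), MI 4 (0.0524 and 0.0534), MI_soft 1 (0.0747 to 0.0965), MI_soft 2 (0.0532 to 0.0901), MI_soft 3 (0.0777 to 0.08), MI_soft 4 (up to 0.12), MI_stiff 1 (up to 0.0703), MI_stiff 2 (up to 0.101), MI_stiff 3 (0.0538 to 0.101) or MI_stiff 4 (up to 0.147). Without the low-detection libraries, MI_soft 4 among them, 243 genes changed and the 11 were all among them.

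**Figure D4:**
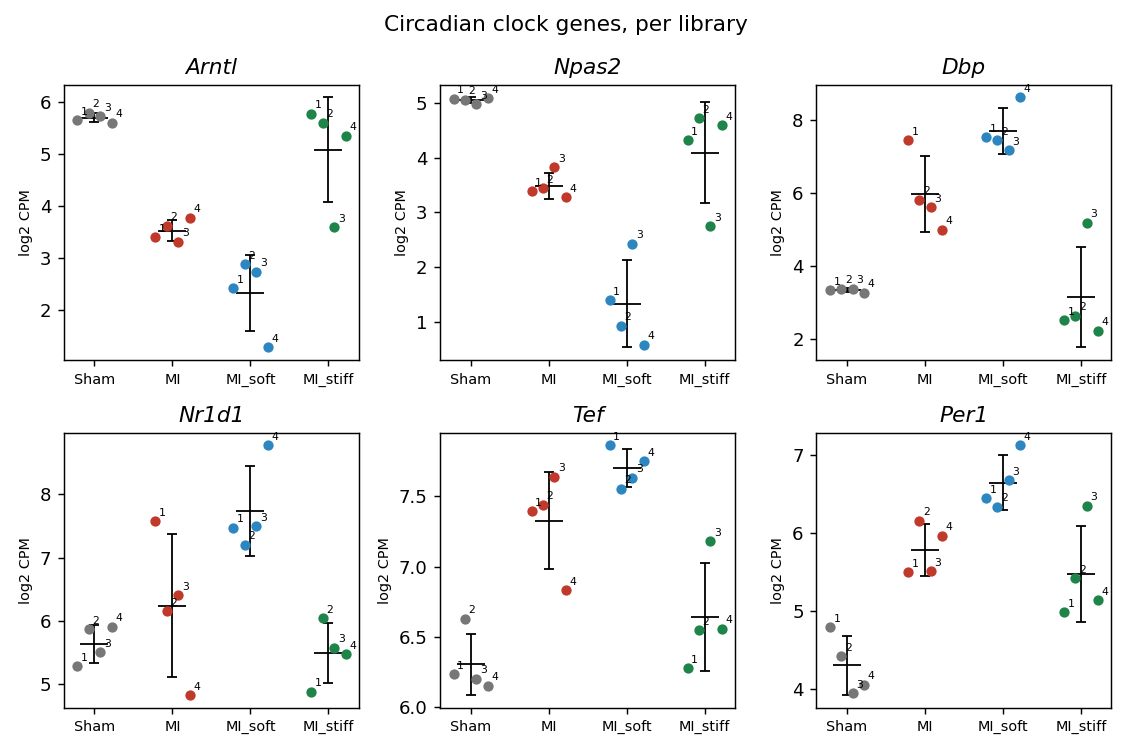
Expression (log2 CPM) of the clock genes Arntl, Npas2, Dbp, Nr1d1, Tef and Per1 in the 4 groups, each point being 1 library with its replicate number, with the mean ± SD of the log2 values (n = 4); Nr1d1, Tef and Per1 were chosen after their values were seen. Dbp lies at 5.19 in MI_stiff 3 and between 2.22 and 2.63 in the other MI_stiff libraries.

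Of 20 lymphocyte genes 0 passed by edgeR over all genes and 4 were lower in MI_stiff adjusted over the list alone (median -1.81), with Jchain at 3.02 ± 1.65 against 125 ± 105 CPM (edgeR adjusted p = 0.0507). Lymphocytes had camera adjusted p = 1.37e-08 and adjusted p = 0.292 with an estimated correlation. Of 12 giant cell genes 5 were higher adjusted over the list alone (median 1.09), with Ctsk at 1.03 ± 0.28 and edgeR adjusted p = 0.124. Giant cells had camera adjusted p = 0.00104 and adjusted p = 0.292 with an estimated correlation. Of 9 epicardial genes 5 were higher adjusted over the list alone (median 1.79), with Msln at 2.14 ± 0.65 and edgeR adjusted p = 0.16. The epicardial list had camera adjusted p = 5.35e-05 and adjusted p = 0.292 with an estimated correlation. Of 23 angiogenic and hypoxia genes 2 rose, Aplnr and Angptl4 (5 adjusted over the list alone). Angiogenic factors had camera adjusted p = 1.39e-05 and adjusted p = 0.292 with an estimated correlation. Of 15 contractile genes 4 were lower adjusted over the list alone (camera adjusted p = 0.00195, and adjusted p = 0.55 with an estimated correlation). Interferon response (10 lower and 1 higher of 21 adjusted over the list alone; camera adjusted p = 0.0122) was lower, with an adjusted p = 0.638 with an estimated correlation, and at 0.0537 without MI_soft 1 and 0.85 without MI_soft 4. Activated fibroblasts were lower (3 of 16 adjusted over the list alone; camera adjusted p = 0.0192, and adjusted p = 0.444 with an estimated correlation; 0.0672 without MI_soft 2, 0.082 without MI_soft 3 and 0.0651 without MI_stiff 3), and so was skeletal muscle (3 of 5; 0.0192, and adjusted p = 0.563 with an estimated correlation; 0.0618 without MI_soft 2). MHC class II was lower (0 of 10 adjusted over the list alone; camera adjusted p = 0.0255, and adjusted p = 0.637 with an estimated correlation), a call lost without MI 1 (0.122), MI 3 (0.0577), MI_soft 1 (0.0745), MI_soft 2 (0.0618), MI_soft 4 (0.246) or MI_stiff 2 (0.384). Endothelial cells were higher (0 of 15 adjusted over the list alone; camera adjusted p = 0.033, and adjusted p = 0.505 with an estimated correlation), a call lost without MI_soft 1 (0.0979), MI_soft 2 (0.0717), MI_soft 3 (0.151), MI_stiff 2 (0.102) or MI_stiff 3 (0.092). Hmox1 stood at 97.5 ± 21.1 against 36.0 ± 11.4 CPM (edgeR adjusted p = 0.0507), and Nppb at 233 ± 55.1 against 522 ± 123 CPM (adjusted p = 0.068). Nppa (-1.17 ± 0.49), Ccn2 (-1.15 ± 0.42), Myh7 (-0.86 ± 0.31), Col3a1 (-0.19 ± 0.23), Cd68 (0.04 ± 0.49), Atp2a2 (0.15 ± 0.24), Col1a1 (0.25 ± 0.34), Postn (0.37 ± 0.34), Myh6 (0.44 ± 0.39) and Gja1 (0.69 ± 0.30) had adjusted p-values of 0.225 to 0.977.

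Comparing each hydrogel group with Sham addressed what differed from uninjured heart. MI_soft differed from Sham in 2965 genes (1860 higher and 1105 lower) and MI_stiff in 2410 (1450 higher and 960 lower) by edgeR's quasi-likelihood test. These counts do not rank the gels by distance from Sham, since the order reversed with only the 2 groups compared (3624 and 4523) and without the low-detection libraries (4455 and 4986). The share of higher genes, 62.7% and 60.2%, was 50.8% and 50.3% with limma-voom (1628 and 1576, and 1238 and 1225), 71.9% and 82.1% on log2(TPM + 1) (1633 and 637, and 1781 and 389), and 79.1% and 88% on log2(TPM + 0.1) (1627 and 429, and 1716 and 235). Macrophage genes were higher in both, with 19 of 22 called in MI_soft (21 adjusted over the list alone; camera adjusted p = 9.77e-13, and adjusted p = 0.128 with an estimated correlation) and 21 of 22 in MI_stiff (22 adjusted over the list alone; 6.68e-14, and adjusted p = 0.101 with an estimated correlation). Of the 12 giant cell genes 7 rose and 1 fell in MI_soft (7 and 1 adjusted over the list alone; camera adjusted p = 0.000396, and adjusted p = 0.134 with an estimated correlation) and 8 rose and 1 fell in MI_stiff (8 and 1 adjusted over the list alone; 1.27e-06, and adjusted p = 0.0691 with an estimated correlation). Fatty acid oxidation genes fell in both, 21 of 26 in MI_soft (23 adjusted over the list alone; camera adjusted p = 1.55e-11, and adjusted p = 0.128 with an estimated correlation) and 19 in MI_stiff (23 adjusted over the list alone; 1.74e-11, and adjusted p = 0.101 with an estimated correlation). Of 20 lymphocyte genes 7 rose in MI_soft (7 adjusted over the list alone; camera adjusted p = 0.000903, and adjusted p = 0.295 with an estimated correlation) and 0 by edgeR in MI_stiff (median 0.16, mean 0.13, test direction lower, camera adjusted p = 0.71). None of these called lists held with an estimated correlation. Of all lists, 1 held its call in MI_soft and 2 in MI_stiff (lowest camera adjusted p 0.0234 and 0.0347).

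Changes against Sham were shared between the groups, which share the Sham libraries. MI and MI_soft had 2377 calls in the same direction (375.4 higher and 181.5 lower expected of independent lists), MI and MI_stiff 2051 (292.7 and 157.7) with 2 in opposite directions, and MI_soft and MI_stiff 1760 (237.1 and 93.25). All 3 groups shared 1064 higher and 567 lower genes. In 20 simulations of unchanged groups the highest shared count was 0, and with the Sham libraries split between the comparisons the counts were 1134 to 1166, 907 to 989 and 760 to 822. Neither expected value takes account of both the shared libraries and the real changes.

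Whether a hydrogel moved ligation genes back towards Sham was asked with the MI libraries shared between the comparisons. Of the 135 genes that differed between MI_stiff and MI, 98 had changed in the opposite direction in MI against Sham and 16 in the same direction. Of the 98, 77 rose with ligation and fell with the gel, as Nppb, Thbs4, Tagln and Fos did, and 21 fell with ligation and rose with the gel, as Atp2a2 did. Independent lists would give 25.1, a value that takes no account of the shared MI libraries, so the excess of 98 over it is no measure of an effect of the gel. Most of the genes named here have unsteady calls in MI_stiff against MI. Of the 16 fits with 1 library left out, 12 lost the call of Nppb, 12 that of Tagln, 11 that of Fos, 13 that of Atp2a2 and 1 that of Thbs4. The covariance of the log2 differences across genes was -0.71 against a simulated -0.12, a difference of -0.59. With 2 MI libraries for each comparison, so that none was shared, it was -0.475 on average (-0.597 to -0.347 over 6 splits), 64.5 to 80% of ligation genes had the opposite sign, and the count was 0 to 381. Each pair still held at least 1 of the low-detection libraries MI 2, 3 and 4, and the simulations held no such libraries. Neither the split nor the simulated values in this paragraph can therefore separate low detection in MI from an effect of a gel. The correlation of the log2 differences across genes was -0.632 against a simulated -0.504, and -0.358 on average when split. For MI_soft 2 of its 3 genes moved back (0.605 expected of independent lists), the covariance was -0.503 against a simulated -0.121, a difference of -0.382, and split it was -0.268 (-0.425 to -0.104), with 51.4 to 76.6% opposite and 0 to 288 called. Its correlation, -0.486, was not past the simulated -0.504, and was -0.222 on average when split. The count of genes moved back was between 6 and 999 for MI_stiff and between 0 and 1091 for MI_soft with 1 library left out, and without the low-detection libraries 168 and 9. The gels' differences from MI had a covariance of 0.419 against a simulated 0.121, a difference of 0.298, and of 0.184 (0.0912 to 0.269) with the MI libraries split. Their correlation was 0.66 against a simulated 0.504, and 0.233 on average when split. The gels shared 1 lower gene, 0.0208 expected.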

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

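The tests of a general rise of macrophage genes, of an exchange of MI 1 and MI_soft 4 and of a wrong label of MI 1 alone, and the choice of the genes examined for single deviating libraries, came only after the results were seen.

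Giant cell and osteoclast-type genes were higher in MI_stiff than in MI, with a median log2 difference of 4.81 over the called members. Against MI 1 alone, the MI library with most genes detected, the median was 2.86 (range 1.21 to 4.56), and 80% of the called members lay above MI 1 in all 4 MI_stiff libraries. MI_stiff 2 was the lowest of these, with a list mean log2 CPM of 2.983 against 4.444 to 4.517 in the others and 2.603 in MI 1. Over all 12 tested members the median difference of mean log2 CPM was 1.08 against MI 1 and 1.93 against all MI libraries, with 10 of 12 higher than MI 1. The value over the called members met the bound set in advance against low detection as the cause, but that bound was wrong because it rests on a single reference library, which itself lies near MI_soft, so low detection in MI 2, 3 and 4 cannot be told apart from an effect of the gel. A larger number of macrophages of every kind is also open: the median of the 12 giant cell members was 1.76 and that of general macrophage members 0.918, a difference of 0.842 with a 95% bootstrap interval over genes of -0.296 to 4.11. The stiff gel itself stays among the open explanations.

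The clock genes Arntl, Npas2 and Dbp differed between MI_stiff and MI_soft. Low detection in MI_soft 4 is argued against, since without it the median size of their log2 differences was 2.63 against 2.87, with Arntl (edgeR adjusted p = 0.00635) and Npas2 (0.0245) still called and Dbp at 0.0517. A shift of circadian phase between the groups may account for the pattern: the 8 other clock genes tested all lay in the direction named in advance, with a median signed difference of 1.06 (95% bootstrap interval over genes 0.535 to 2.34). Genes of the same libraries are not independent replicates, so this interval does not measure the spread between libraries. The differences of these 8 genes ran from 0.485 for Per3 to 3.04 for Ciart, and their edgeR adjusted p-values, from 0.0507 for Nr1d1 to 0.716 for Per3, all missed the threshold. Nr1d2 and Hlf are not analysed here. The labels used here give no time of collection, so a difference in the hour of sampling and an effect of the gels on the clock both stay open. Arntl, Npas2 and Dbp also stood apart between Sham and MI, which had no gel. Their mean log2 CPM was 5.69, 5.06 and 3.33 in Sham and 3.52, 3.49 and 5.97 in MI. It was 5.07, 4.1 and 3.13 in MI_stiff and 2.32, 1.33 and 7.7 in MI_soft. A difference in the hour of sampling, if there was one, could thus enter the comparisons with Sham and MI too. MI_stiff 3 lay apart from the other MI_stiff libraries, with log2 CPM of 3.58 against 5.35 to 5.77 for Arntl.

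MI 1 lay nearer to MI_soft 1, 2 and 3 (correlations across genes of 0.957 to 0.964) than to MI 2, 3 and 4 (0.873 to 0.898). Genes with few counts missing from MI 2, 3 and 4 are argued against as the whole cause, since over the 2844 most abundant genes the smallest root mean square difference of MI 1 from those libraries was 1.69 times the largest from MI_soft 1 to 3. An exchange of MI 1 and MI_soft 4 is not excluded, and values of MI_soft 4 went both ways. MI_soft 4 correlated less with MI 2 to 4 than with MI_soft 1 to 3 (mean difference -0.0417), without overlap over all genes (0.811 to 0.85 and 0.855 to 0.892) and with overlap over the abundant ones (0.663 to 0.793 and 0.772 to 0.843). On the axis from the mean of MI 2 to 4 (0) to that of MI_soft 1 to 3 (1), MI_soft 4 lay at 0.924 over the abundant genes. That is against 0.0621 to 0.321 for MI 2 to 4 and within the 0.831 to 1.03 of MI_soft 1 to 3. Each of MI 2 to 4 and of MI_soft 1 to 3 was placed on an axis drawn without it, so these places come from other axes than that of MI_soft 4. Over all genes MI_soft 4 lay at 0.593, against 0.213 to 0.415 for MI 2 to 4 and under the 0.845 to 0.988 of MI_soft 1 to 3. Its gap from MI 2 to 4 was smaller than the range of MI 2 to 4, which keeps the exchange open. MI_soft 4 stood apart from MI 2 to 4 in macrophage genes (mean log2 CPM 6.55 against 4.04 to 4.51), lymphocyte genes (2.80 against -1.39 to -0.327), Mmp12 (6.04 against 0.21 to 2.07) and Npas2 (0.577 against 3.28 to 3.83). It lay with MI 2 to 4 in calcium handling genes (4.911 against 4.048 to 5.389, and 5.778 to 6.24 in MI_soft 1 to 3). The same held for genes of ribosomal proteins (6.532 against 6.195 to 6.677, and 5.938 to 6.144 in MI_soft 1 to 3). MI_soft 4 and MI 2 to 4 are also the low-detection libraries, so these likenesses cannot tell an exchange from low detection. A wrong label of MI 1 alone is open too, because its highest correlation with MI_soft 1 to 3 lay only 0.00144 under the lowest among these. No biological explanation was tested, and single genes of MI 1 went both ways. Arntl (log2 CPM 3.39) and Npas2 (3.39, against 3.28 to 3.83 in MI 2 to 4 and 0.577 to 2.43 in MI_soft) were like those in the other MI libraries. Mmp12 (4.32) lay between MI 2 to 4 and MI_soft (6.04 to 8.05), and Dbp (7.45) was in the range of MI_soft (7.18 to 8.63).

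For each count of changed genes, the 35 splits of the 8 libraries into 4 and 4 were compared. The real split ranked first for MI against Sham (1 split with as many, the real 4165, highest other 13) and MI_soft against Sham (1 split, 2965, highest other 0). It also did for MI_stiff against Sham (1 split, 2410, highest other 1) and MI_stiff against MI_soft (1 split, 11, highest other 2). These counts met the bound set in advance against chance. A first rank among 35 splits is the most this test can give, so chance is not excluded. Mixed splits also put real differences between groups into the spread, which lowers their counts. The bound was not met for MI_soft against MI, where 3 splits gave as many as the real 3 and the highest other 1085. Nor was it met for MI_stiff against MI, where 2 splits gave as many as the real 135 and the highest other 668. The split with 1085 genes is that in which MI 1 and MI_soft 4 change places, and the one with 668 puts MI 1 with MI_stiff 2, 3 and 4. Splits that call several times the real count point to a structure of the samples. Both part MI 1 from MI 2, 3 and 4. The first also sets the 4 low-detection libraries against the rest, and the other puts MI 2, 3 and 4 with MI_stiff 1, which has the fewest genes of MI_stiff (12019), so the place of MI 1 and gene detection are not separated by them.

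Single libraries that lay far from the other 3 of their group were sought among 83 genes and 5 library measures in 4 groups. Of 352 groups tested 26 had such a library, where chance gives about 1 in 20 groups, or 17.6. That rate takes no account of values at 0 counts or of the choice of genes after their values were seen. The value of 17.6 is therefore no exact expectation. The ratio of the gap to the range was 0.998 for MI_soft 4 and 0.935 for MI_stiff 1 in median correlation with the own group (0.874 against 0.965, and 0.931 against 0.947 to 0.948), and 0.854 for the total count of MI 3. In MI_stiff 2, lower than the rest of its group, it was 0.882 for Cd14, 0.844 for Lyz2, 0.884 for Mmp12, 0.834 for Ocstamp and 0.915 for Il1rn. In MI 1 it was 0.835 for Gfod1, 0.911 for Cirbp, 0.871 for Ighe, 1 for Dcstamp and 1 for Ocstamp, with Ighe at a log2 CPM of 7.7 against 1.82 to 2.58. In MI_soft it was 0.883 for Tbx20 and 0.884 for Iqgap2 in library 4, 0.943 for Mmp12 in library 2 and 0.894 for Slc2a1 in library 3. In the other MI_stiff libraries it was 0.852 for Gfod1 in library 1, 0.849 for Plau and 0.862 for Dbp in library 3 and 0.919 for Cyp21a1 in library 4. In Sham it was 1 for Ca3 and 0.927 for Cyp21a1 in library 3, 0.898 for Hadh and 0.925 for Plau in library 2 and 0.921 for Nppb in library 4. The ratio of 1 for Ca3, Dcstamp and Ocstamp came from 0 counts in the other libraries of the group. Tbx20 and Iqgap2 in MI_soft 4 and Gfod1 in MI_stiff 1 stood apart with 0 counts themselves.

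The effects of the gels against MI differed, by the edgeR test of MI_stiff against MI_soft, by log2 2.87 for Arntl, 2.82 for Npas2, 2.2 for Ucp3, 2.07 for Aplnr, 1.98 for Angptl4, 1.83 for Atf3, 1.69 for Fmo5, -1.81 for Nupr1, -2.64 for Ccl19, -4.11 for Dbp and -7.8 for Ighe.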

How the results depend on the processing

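The fits without the low-detection libraries, with library quality weights, without mitochondrially encoded genes and with the length trend removed were chosen after the data were seen; the causes of the changes below were not tested.

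The counts of genes for MI against Sham stayed within 1.5 times of 4165 in all settings run (3103 to 5054). For MI_soft against MI, with 3 genes, the count was 293 with DESeq2, 7 with limma-voom, 5 on log2(TPM + 1), 0 on log2(TPM + 0.1), 0 with only the 2 groups compared, 11 without the low-detection libraries, 408 with quality weights and 10 with the length trend removed. For MI_stiff against MI, with 135, it was 583 with DESeq2, 82 with no low-count filter, 86 with limma-voom, 47 on log2(TPM + 0.1), 13 with only the 2 groups compared, 215 without the low-detection libraries and 267 with quality weights. For MI_stiff against MI_soft, with 11, it was 278 with DESeq2, 32 with upper-quartile factors, 17 with limma-voom, 7 on log2(TPM + 0.1), 243 without the low-detection libraries, 509 with quality weights and 26 with the length trend removed. Against Sham, MI_soft gave 4455 without the low-detection libraries and 6119 with quality weights, and MI_stiff gave 4523 with only the 2 groups compared, 4986 without the low-detection libraries and 5188 with quality weights. Ligation genes moved back were 198 (MI_soft) and 425 (MI_stiff) with DESeq2, 9 and 168 without the low-detection libraries, and 81.5 (median) for MI_soft with the MI libraries split.

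With the replicate number as a block the counts were 0 for MI_soft against MI, 34 for MI_stiff against MI and 3 for MI_stiff against MI_soft, and 0 and 22 genes moved back. The numbers do not pair the libraries: 5 of 24 pairs with the same number had a correlation over 0.1, and 2 of 16 libraries had their best match under their own number, so a block removes degrees of freedom without a shared source.

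With 1 library left out, the counts ranged from 0 (without Sham replicate 1, for example) to 1508 (without MI replicate 1) for MI_soft against MI, from 11 (without MI replicate 4) to 1253 (without MI replicate 1) for MI_stiff against MI and from 4 (without MI_stiff replicate 4) to 57 (without MI replicate 3) for MI_stiff against MI_soft. Genes moved back ranged from 0 to 1091 for MI_soft and from 6 to 999 for MI_stiff.

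Without the low-detection libraries the direction of camera's test turned for 26 of 186 list results, of which 21 were called in neither fit. The 5 called in either were lymphocytes (camera adjusted p = 0.035) in MI against Sham, macrophages (0.684) and epicardium (0.0036) in MI_soft against MI, and macrophages (0.687) and lymphocytes (0.00137) in MI_stiff against MI. For lymphocytes in MI_stiff against MI, the main median (-0.194) and mean (-0.143) were lower already, while the test direction was higher. In comparisons other than MI_soft against MI this fit also called 10 lists that had not passed. These were smooth muscle (0.0313, higher) in MI against Sham, and collagens (0.0116, lower), angiogenic factors (0.0151, higher) and atrial myocardium (0.0446, lower) in MI_stiff against MI. In MI_stiff against MI_soft they were wall stress (0.0247, lower), TGF-beta signalling (0.0247, lower), fatty acid oxidation (0.00296, higher), respiratory chain (0.0414, higher), cell cycle (0.0414, higher) and Schwann cells (0.043, lower). Calls were lost in this fit as well. Among them were MHC class II and interferon response (lower) in MI_stiff against MI_soft, and neutrophils (higher) in MI_soft and in MI_stiff against Sham. The log2 difference in MI against Sham turned to -0.568 for Rgcc and -0.156 for Fabp4. Of 186 list results, 92 lost their call with an estimated correlation, and with fry in its directional form 26 lost and 12 gained one. Camera called 10 lists in MI_soft against MI, 15 in MI_stiff against MI and 10 in MI_stiff against MI_soft, where directional fry called 5, 3 and 1. Against Sham, camera called 21, 21 and 19 lists for MI, MI_soft and MI_stiff, and directional fry 24, 27 and 22.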

Other observations

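The ribosomal genes, and the fits without the low-detection libraries and with a trend on gene length removed, were chosen after the data were seen; no tests beyond these are given in this part.

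Genes of cytosolic ribosomal proteins rose with ligation: of 90 tested, 66 rose and 3 fell in MI against Sham by edgeR's test, with a median log2 difference of 1.35. Against Sham 64 rose and 2 fell in MI_soft (median 1.13) and 32 rose and 2 fell in MI_stiff (median 0.648). In MI_stiff against MI 11 fell and 0 rose (median -0.722). The mean log2 CPM of these genes was highest in the low-detection libraries (6.195 to 6.677 in MI 2, 3 and 4 and 6.532 in MI_soft 4), against 5.997 in MI 1, 5.938 to 6.144 in MI_soft 1 to 3, 5.57 to 6.027 in MI_stiff and 5.08 to 5.311 in Sham. Without these libraries, with MI 1 as the single MI library, 52 rose and 2 fell in MI against Sham (median 0.978), 67 and 4 in MI_soft against Sham (0.928) and 47 and 3 in MI_stiff against Sham (0.666), and 3 fell in MI_stiff against MI (-0.266). These genes are short, with a median length percentile of 3.9 among the tested genes.

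The 79 genes that fell in MI_stiff against MI had a median log2 difference of -1.38 and a median length percentile of 17. With a trend on gene length removed, 86.3% of the median was kept and 63 of the 79 stayed past the threshold. Their median difference of mean log2 CPM was -1.3 against all MI libraries and -0.957 against MI 1 alone, which is 73.5% of it.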
